A study of Mus musculus with 18 samples.

How the data were processed

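RNA of mouse ovaries had been hybridised to 2 oligonucleotide chip types that carry Affymetrix control probe sets, and 1 array of each type was deposited for each of 9 conditions, 18 arrays in all. The conditions were wild-type and LHCTP transgenic ovaries of CF-1 mice and of CF-1xC57BL/6 hybrids at 2 and 5 months, and an hCG-treated CF-1 transgenic condition. The groups and the pathology come from the sample titles, sources and descriptions. For the chip B array of the tumour, the description gives another age than the title and the source, which were followed. The labels name no replicate animals and no pooling, and no condition had a second array of the same chip type, so that spread could be estimated only between conditions.

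The deposited values are intensities on a linear scale, 1 per probe set and array, with 13.6% to 30.1% of them below 0, as after a background subtraction. How the authors computed the intensity values, and with which software and scaling, is not given in the sources used here. The arrays had not been brought to a common level, since their trimmed means on one chip type differed by up to 1.94-fold. The highest value of an array ran from 24574.5 to 40882.5 units on chip A and from 25652.5 to 41833.2 units on chip B, and bright probe sets near that level are compressed.

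Chip A had 6584 and chip B 6595 probe sets. On each chip 55 Affymetrix control probe sets and 21 named probe sets present on both chips were left out, 76 in all. A probe set with any of the 3 missing values was not tested. Genes were named only from the platform annotation supplied, updated by Entrez gene number through gene models of mouse assembly GRCm38.p6. Of the probe sets, 5560 on chip A and 2031 on chip B had 1 gene symbol, 197 and 27 had several, and 827 and 4537 had none and stay unnamed here. The update matched 7544 of the 7561 annotation entries with 1 symbol. Genes with several probe sets were represented in lists by the one with the highest mean, and levels were compared only within a probe set.

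Each chip type was scaled to a common trimmed mean, from the 2nd to the 98th percentile. Values were then raised to a floor and taken to log2. The floor was the median over arrays of the larger of the absolute 5th percentile and the 25th percentile, 183.8 units on chip A and 290.7 on chip B. The detection limit was 2 floors. Probe sets at or above it on at least 2 of 9 arrays were tested, 4122 on chip A and 2286 on chip B, 6408 in all. Levels printed are scaled intensities before the floor, while log2 differences are floored, which understates those of low probe sets. Where an array lay under the floor, a fold was computed against the floor and is given as at least that size.

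Genotype, strain and age were fitted as additive terms to the 8 untreated arrays of each chip type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 4 residual degrees of freedom, and p-values were adjusted over both chip types by the Benjamini-Hochberg method at a threshold of 0.05. The residual spread holds the interactions of the 3 factors. In separate fits with 3 residual degrees of freedom, chosen after the data were seen, the interaction of genotype with age gave 0 probe sets past limma's threshold and 177 at an unadjusted p under 0.05, and that of genotype with strain 0 and 348, where 320 are expected by chance. The p-values measure spread between single samples of different conditions, not between animals of one condition.

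A set of 19 gene lists, from steroidogenesis to cell types the ovary and adjoining tissue could hold, was tested for genotype with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, over lists with at least 5 measured genes. Fry, which asks whether a list moves on balance in one direction, gave adjusted p = 0.0636 for epithelium and oviduct and 0.0906 for adipocyte, smooth muscle, lymphocyte and erythroid genes. Comparisons with a single array on either side had no test and used rules of size. A probe set counted for the tumour when it stood at least 3-fold beyond every other array, for the luteoma pair when both stood at least 2-fold beyond the other 7, and for 2 arrays when they differed at least 3-fold, each with the brighter side at the detection limit. List medians of such comparisons are given with their percentile among 10000 random lists of the same size and level. Random lists do not keep the joint movement of related genes, so these percentiles are descriptive and are not p-values. Extreme ones were common, and the immediate early and heat shock list reached 0.06 and 99.99 in 2 comparisons.

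Named genes followed a rule. For genotype these were genes past the threshold that moved alike in the 4 pairs, or, if fewer than 10 passed, the 10 with the lowest p. For the tumour they were the 12 largest gaps on either side, for the luteoma pair the 10 largest on either side, and for age and strain the 5 largest changes on either side past the threshold. List members could be named anywhere. Lists, tests, named-gene rule and most alternatives were set before the data were examined. The alternatives were quantile normalization, no scaling, a floor of 20 units, a doubled floor, an asinh scale, no filter, eBayes with trend and robust variances, a pair block, no covariates, the hCG array added, each array left out, a fold limit raised by 1.5, and other list settings. A term for 3 arrays with a shared control profile, their removal, and list tests without each array were added after the data were seen.

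The steps were tested on simulated data built on the real levels. For the genotype fit over 6408 probe sets, limma recovered 67.6% of 2-fold, 98.4% of 4-fold and 100% of 8-fold changes, with 12 false among 187 calls. The 3-fold rule for the tumour recovered 100 of 100 probe sets changed 8-fold among 13027, all of them in probe sets above 8 floors. The noise there had a fixed SD not taken from the data, and the change lay far above the limit. Full recovery was therefore nearly certain from the start. Camera recovered the 1 list changed 2-fold. The simulated noise was independent between probe sets and held no interactions of the 3 factors, and the limma data had no floor. These shares therefore do not carry over to the real arrays, where Dcpp1, lower by at least 8.01-fold in transgenic ovaries, did not pass. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.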

Results

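Gene expression was measured in whole ovaries of mice that hypersecrete luteinizing hormone (LH) from a transgene, named LHCTP in the labels, and of wild-type mice. The animals were CF-1 mice or CF-1xC57BL/6 hybrids, aged 2 or 5 months. The labels describe the transgenic ovaries as cystic at 2 months in both strains, as a granulosa cell tumour at 5 months in CF-1, and as a luteoma at 5 months in the hybrid. A further CF-1 transgenic sample at 5 months had been treated with human chorionic gonadotropin (hCG), a hormone that acts on the LH receptor, and is also described as a luteoma. Each of the 9 conditions was hybridised to 1 array of each of 2 chip types, A and B, which gave 18 arrays and no repeat of any condition. The trimmed mean intensity before scaling ran from 907 to 1756 units on chip A and from 542 to 921 units on chip B. After scaling, 54.5% to 57.9% of the probe sets on chip A and 28.0% to 29.6% on chip B stood at or above the detection limit.

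The first comparison asked what differs in LH-hypersecreting ovaries whatever the strain and age. Genes of epithelium and oviduct fell in the transgenic ovaries, with a median log2 difference of -1.13 over 12 measured genes. Adipocyte genes fell by 1.41 over 6 genes, smooth muscle genes by 0.66 over 6 genes and lymphocyte genes by 0.40 over 5 genes, all as median log2 differences, and erythroid genes rose by 0.30 over 5 genes. These 5 calls rest on camera with a preset correlation, at adjusted p = 8.2e-09 for epithelium and oviduct, 0.000243 for adipocyte, 0.000243 for smooth muscle, 0.00459 for lymphocyte and 0.00373 for erythroid genes. All 5 were lost in camera with an estimated correlation, at adjusted p = 0.236 for epithelium and oviduct and 0.298 for each of the other 4 lists. They were also lost with fry, a second list test of movement in one direction, where the adjusted p was 0.0636 for epithelium and oviduct and 0.0906 for the other 4.

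In the epithelium and oviduct list, 7 of the 12 members fell when p was adjusted over the list alone and 0 when it was adjusted over all probe sets tested. Krt8, a keratin of simple epithelia, averaged 2611 ± 577 units (SD, n = 4) in wild-type and 961 ± 261 units (SD, n = 4) in transgenic ovaries. Cdh1, which encodes E-cadherin of epithelial junctions, averaged 1401 ± 491 units in wild-type and 469 ± 289 units in transgenic ovaries (SD, n = 4 each), and Pax8, a transcription factor of the oviduct and other Müllerian epithelia, averaged 652 ± 91.4 and 259 ± 39.8 units (SD, n = 4 each). Pax8 lay under the floor in the CF-1 cystic ovary, the hybrid cystic ovary and the hybrid luteoma, and Cdh1 in the tumour. The list's median difference was -0.99 in the CF-1 pair and -1.04 in the hybrid pair at 2 months, -1.11 in the CF-1 pair at 5 months and -1.22 in the hybrid pair at 5 months. In the same order, 10, 7, 10 and 11 of the 12 members were lower and 2, 5, 1 and 1 were higher. In the hCG-treated transgenic ovary the median was -0.02 relative to the CF-1 wild type of 5 months. With the floor doubled, which sets more members to the floor, the list's median difference was -0.39.

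Among the adipocyte genes, 3 of 6 fell with p adjusted over the list alone and 0 over all probe sets. Adipoq, the fat-cell hormone adiponectin, read 613, 2037, 1656 and 2156 units in the 4 wild-type ovaries and 317, 154, 329 and 235 units in their transgenic partners. Fabp4, a fatty acid binding protein of fat cells, had a log2 difference of -1.86 and Car3, a carbonic anhydrase abundant in fat, of -2.15. Both are understated, since Fabp4 lay under the floor in the CF-1 cystic ovary and the tumour, and Car3 in the tumour and the hybrid luteoma. The median of this list was -0.52 and -1.98 in the CF-1 pairs of 2 and 5 months and -1.32 and -1.84 in the hybrid pairs. Whether the samples held different amounts of adjoining fat was not tested, so the falls in adipocyte genes cannot be assigned to cells of the ovary. In the smooth muscle list 4 of 6 members fell with p adjusted over the list alone, among them the calponin gene Cnn1 with a log2 difference of -0.97 and Tagln with -0.45. The smooth muscle median was -0.74 and -0.16 in the CF-1 pairs of 2 and 5 months and -0.19 and -0.87 in the hybrid pairs.

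In the lymphocyte list the 2 members that fell with p adjusted over the list alone belong to antibody production, namely Igha, the immunoglobulin A heavy chain, and Jchain, the joining chain of secreted antibodies. Igha averaged 1232 ± 414 units in wild-type and 403 ± 206 units in transgenic ovaries (SD, n = 4 each), and Jchain had a log2 difference of -0.59. The T cell gene Cd3e had a log2 difference of -0.40 and did not pass. The lymphocyte median was -0.51 and -0.82 in the CF-1 pairs of 2 and 5 months and -0.65 and -0.31 in the hybrid pairs. In the erythroid list the 1 member that rose with p adjusted over the list alone was Alas2, the first enzyme of heme synthesis in red cell precursors, with 391 ± 95.8 units in wild-type and 1721 ± 714 units in transgenic ovaries (SD, n = 4 each). Hbb-b2, a beta globin gene, read 18318 units in the CF-1 transgenic ovary of 2 months and 7780 units in its wild type, 30496 against 8538 and 9427 against 7685 units in the hybrid pairs of 2 and 5 months, and 11481 against 12491 units in the CF-1 pair of 5 months, which went the other way. The erythroid median was 0.46 and 1.48 in the CF-1 and hybrid pairs of 2 months and 0.08 and -0.09 in those of 5 months.

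The other 14 lists did not pass. Their adjusted p was 0.109 for endothelium, 0.114 for oocyte, 0.114 for theca and interstitial genes, 0.179 for immediate early and heat shock genes, 0.279 for cholesterol synthesis and uptake, 0.338 for the Wnt pathway, 0.683 for extracellular matrix, 0.685 for steroidogenesis, 0.735 for luteal and LH response, 0.745 for cyclins D and their inhibitors, 0.759 for proliferation, 0.759 for macrophage and antigen presentation, 0.905 for granulosa and growing follicle and 0.935 for the ovulatory response. Median and mean had opposite signs for luteal genes (0.07 and -0.34) and for macrophage genes (0.09 and -0.27), and the ovulatory list had a median of -0.09 with a test direction upward. Some single members of these lists passed with p adjusted over the list alone. These were Bhmt, lower by a log2 difference of -2.03 and under the floor in the tumour, in the luteal list, and Fdft1, which encodes squalene synthase, higher by 0.67, in the cholesterol list. In the immediate early and heat shock list 1 gene passed upward and 4 passed downward, including Hspa1a at -1.14 and Jun at -1.10. Hspa1a lay under the floor in the CF-1 cystic ovary and the tumour. Over all probe sets 0 members of these lists passed. Leaving out 1 array brought further lists past the threshold, namely cholesterol, endothelial and macrophage genes without the CF-1 wild type of 5 months, when 8 lists passed (adjusted p = 0.0243 for each of the 3, macrophage genes upward), and cholesterol (7.3e-05) and endothelial genes (0.000146) without the tumour. The same held for endothelial genes without the CF-1 wild type of 2 months (0.0437), for oocyte genes without the CF-1 cystic ovary (0.0104) or the hybrid wild type of 2 months (0.0242), and for macrophage (0.0319) and immediate early genes (0.0413), both downward, without the hybrid wild type of 5 months. Macrophage genes therefore passed in opposite directions depending on which array was left out.

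At the level of single probe sets, 0 of 6408 passed limma's adjusted threshold of 0.05, and 642 had an unadjusted p under 0.05, against 320 expected by chance, with 300 higher and 342 lower in transgenic ovaries. With trend and robust variances in the same tool 8 passed, and 7 passed without the tumour array, 2 without the CF-1 wild type of 2 months and 1 without that of 5 months. The 10 genes with the lowest p, none of which passed, were Igha, Alas2, Ltf, Dcpp1, Ccn1, Krt8, Cdh1, Ptp4a3, Pax8 and S100g, and each differed in the same direction in all 4 pairs. Their adjusted p ran from 0.0842 to 0.103. Ltf, the secreted iron-binding protein lactoferrin, read 1792 ± 561 units in wild-type and 396 ± 321 units in transgenic ovaries, and Dcpp1 2240 ± 1228 and 239 ± 288 units (SD, n = 4 each). Both lay under the floor in the tumour and the hybrid luteoma, and Dcpp1 also in the hybrid cystic ovary. S100g, a calcium-binding protein, averaged 981 ± 447 units in wild-type ovaries (SD, n = 4) and lay under the floor in all 4 transgenic ovaries, a difference of at least 4.74-fold. Ccn1, a matricellular signalling protein, and Ptp4a3, a phosphatase, were higher in transgenic ovaries, at 646 ± 176 against 224 ± 31.1 units and 1026 ± 413 against 403 ± 122 units (SD, n = 4 each). On the control probe sets of the opposite strand, the CF-1 wild-type, CF-1 tumour and hybrid luteoma arrays of 5 months shared a profile, so that the hybrid 5-month pair set arrays of different profiles against each other. With a term for that profile, which for genotype amounts to leaving out the hybrid wild type of 5 months, limma passed 0 probe sets, 500 had an unadjusted p under 0.05, and the median log2 difference was -1.12 for epithelium and oviduct, -1.34 for adipocyte, -0.52 for smooth muscle, -0.41 for lymphocyte and 0.41 for erythroid genes.

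**Figure D1:**
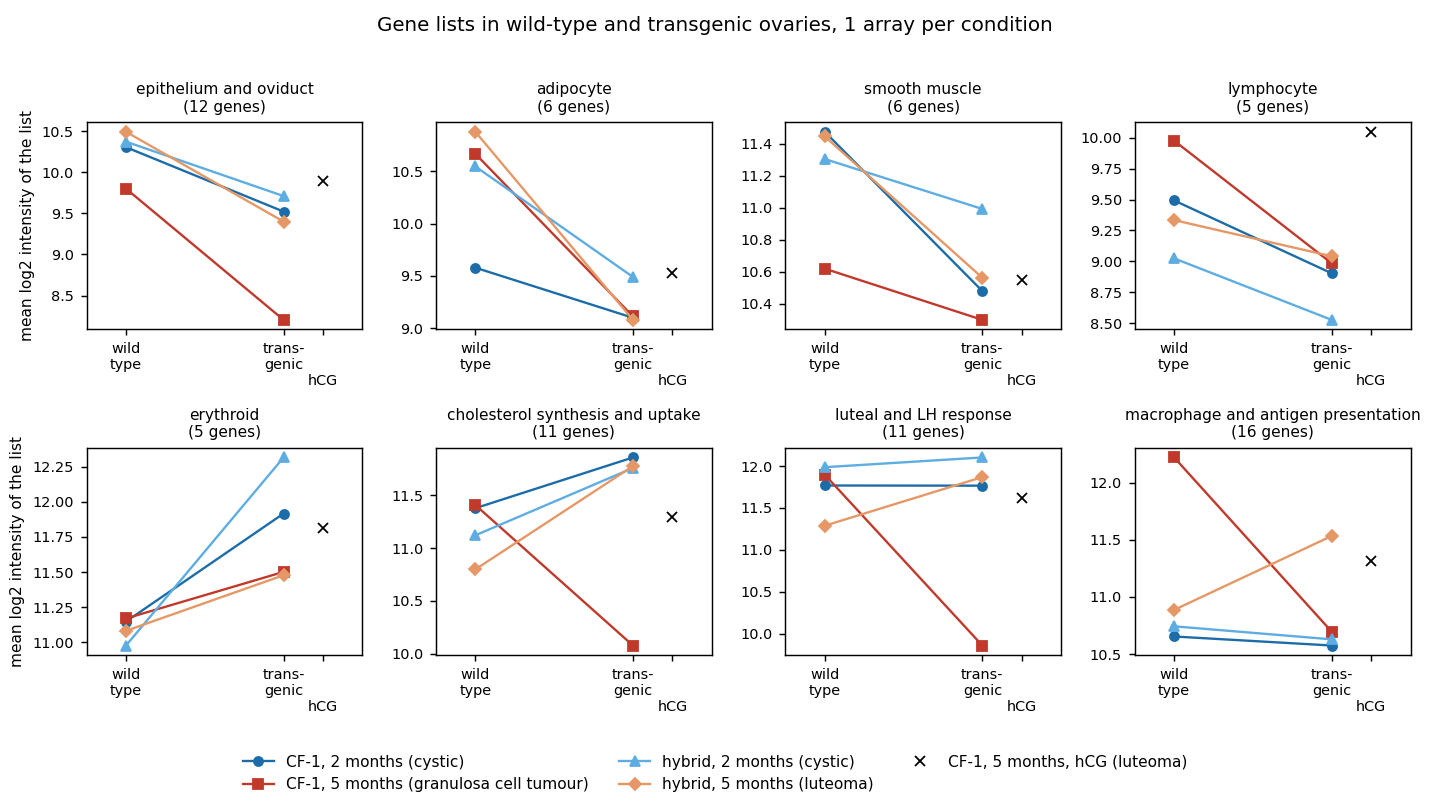
Each panel plots the mean log2 intensity of a gene list on every chip pair of a condition, with lines joining the wild-type and the transgenic ovary of the same strain and age and a cross for the hCG-treated ovary. The epithelium and oviduct level is lower in the transgenic ovary of all 4 pairs, with the lowest value, 8.20, in the tumour, while the luteal level is 9.86 in the tumour and stands between 11.77 and 12.10 in the other 3 untreated transgenic ovaries.

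The CF-1 granulosa cell tumour was then set against the other 8 conditions. Several matrix and signalling genes were highest there. The mean log2 intensity was lowest there for steroidogenesis genes, at 11.688 against at least 12.834 elsewhere, for luteal genes, at 9.862 against at least 11.289, and for epithelium and oviduct genes, at 8.204 against at least 9.400, although single members such as Hsd17b1 were not lowest. The same held for cholesterol genes, at 10.076 against at least 10.798, and for immediate early and heat shock genes, at 10.386 against at least 10.807. Theca and interstitial, ovulatory, oocyte, Wnt pathway and smooth muscle genes were also lowest there. The matrix list, at 11.778 against at most 11.756, hardly stood out. Fn1, the matrix protein fibronectin, read 8249 units in the tumour and at most 2457 units elsewhere, Thbs1 read 5110 units and at most 1370, Lamb1, a laminin chain, read 2211 and at most 584, and Ccn2, a matricellular protein, read 14966 and at most 4320. Star, which carries cholesterol into mitochondria for steroid synthesis, read 188 units in the tumour, close to the floor of 183.8, and between 11263 and 22157 units in the other ovaries. Ptgfr, the prostaglandin F receptor of luteal cells, read 217 units in the tumour and at least 7675 units elsewhere. Against its wild type, the matrix list had a median log2 difference of -0.007 over 24 genes (percentile 51.59), with 11 higher and 12 lower, and Lum, a matrix proteoglycan, read 1479 against 6471 units.

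By the 3-fold rule, 23 probe sets stood above and 39 below every other array, 62 in all, while the corresponding totals for the other 8 arrays ran from 0 to 16. The largest gaps above the next array were those of Bpgm, a bisphosphoglycerate mutase (8.34-fold), Fam20c, a secretory pathway kinase (7.48-fold), and Ptges, a prostaglandin E synthase (7.15-fold). The growth factor Pdgfa stood 5.26-fold above the next array, Mia 5.07-fold, the neurotrophic factor Gdnf 3.64-fold, Nnat 3.56-fold and the hedgehog ligand Dhh 3.36-fold. On the low side Star stood 59.9-fold below the next lowest array, Ptgfr 35.3-fold, Idi1, an enzyme of isoprenoid and cholesterol synthesis, 5.80-fold, these 3 imprecise because the tumour read under the detection limit of 2 floors, Lsr 5.08-fold, Ephx2, the soluble epoxide hydrolase, 5.08-fold and S100a6 4.28-fold. Ovgp1, the oviduct-specific glycoprotein, lay under the floor in the tumour and at least 31.7-fold lower than elsewhere. Also under the floor there were Abcb1b, a drug efflux transporter (at least 15-fold lower), Plet1 (at least 8.53-fold), the keratin genes Krt19 (at least 6.74-fold) and Krt18 (at least 6.26-fold), and Tlcd4 (at least 4.45-fold). Fn1 and Dhh met the rule on the high side and Anxa2 on the low side on both chip types. There was 1 tumour array per chip type, so these differences have no replicate check and no p-value. The count depended on the floor, since with a floor of 20 units it was 216 for the tumour and 209 for the hCG-treated ovary.

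**Figure D2:**
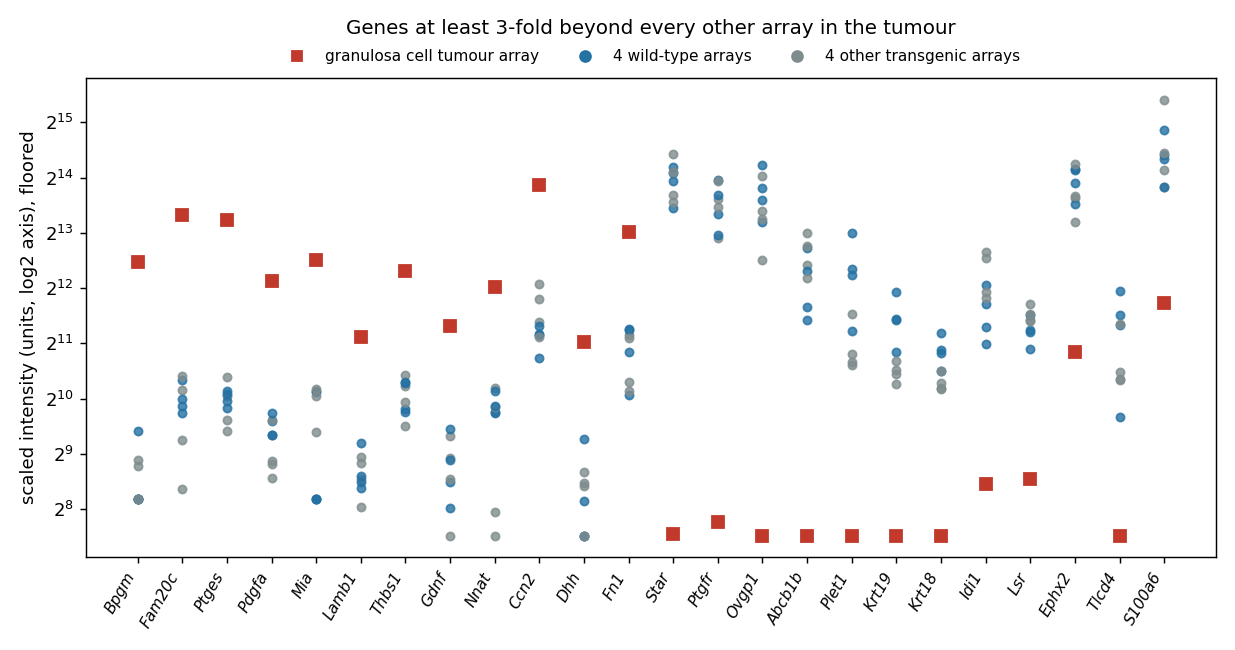
Scaled intensity, on a log2 axis with values under the floor drawn at the floor, of the 12 named genes furthest above and the 12 furthest below every other array in the granulosa cell tumour. Red squares are the tumour array, blue circles the 4 wild-type and grey circles the 4 other transgenic arrays; Star reads 188 units in the tumour and at least 11263 units elsewhere.

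Against its wild-type partner, the tumour had 102 probe sets at least 3-fold higher and 193 at least 3-fold lower. Granulosa cell genes were higher, with a median log2 difference of 0.66 over 14 genes, at percentile 100 of random lists of equal size and level, with 9 members higher and 5 lower. Such percentiles are descriptive, since random lists lack the joint movement of related genes. The mean level of this list in the tumour, 11.462, equalled that of the hybrid wild type of 5 months, and that of its own wild type, 11.107, was the lowest of the 4 wild types. Inhba and Inhbb, the activin subunits, read 12028 and 10279 units in the tumour against 3080 and 4135 units in the wild type, Hsd17b1, which makes estradiol from estrone, read 16047 against 4478 units, and Fst, the activin-binding follistatin, 2804 against 1045 units. Other members went the opposite way, with Wt1 at 1219 against 5767 units and Amh, the anti-Müllerian hormone, at 415 against 1157 units. Steroidogenesis genes had a median of -1.22 (percentile 0.01), with Hsd3b1 at 1150 against 22977 units, Cyp11a1 at 10175 against 23730 units and Cyp17a1 at 1727 against 3968 units. Cholesterol synthesis and uptake genes had a median of -0.86 (percentile 0.02), and Sqle, Hmgcs1 and Dhcr7 read 411, 2678 and 327 units against 1765, 14675 and 4468 units. Immediate early and heat shock genes, which respond to tissue handling, had a median of -0.62 (percentile 0.06). All 16 macrophage and antigen presentation genes were lower on the probe set used for the list, with a median of -0.92. The class II genes Cd74 and H2-Aa read 860 and 422 units against 12507 and 9850 units. H2-Eb1, also of class II, read 815 against 3887 units on that probe set but 2012 against 1789 units on another. The wild-type array itself had the highest level of that list among the 9 arrays, a mean log2 intensity of 12.22. Values of Cyp11a1 and Fdx1 lie near the top of the scale on several arrays, where differences are compressed.

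The remaining transgenic ovaries were compared with their wild types in the same way. At 2 months the cystic ovaries had 48 probe sets higher and 35 lower by at least 3-fold in CF-1, and 76 higher and 76 lower in the hybrid. Cholesterol synthesis and uptake genes were higher in both, with median log2 differences of 0.74 over 11 genes in CF-1 and 0.49 in the hybrid, at percentiles 100 and 99.9. Endothelial genes had medians of 0.39 (percentile 97.58) and 0.46 (percentile 98.79), and macrophage genes of 0.39 in CF-1 (percentile 99.98) and 0.11 in the hybrid (percentile 83.18). The mean log2 intensity of the macrophage list in CF-1 went the other way, from 10.654 in the wild type to 10.575. Inhbb read 1190 against 4839 units in the CF-1 pair and 1331 against 5454 units in the hybrid pair, and Amh 2916 against 1398 and 3913 against 1444 units. The secreted signal Wnt4 read 2318 against 408 units in CF-1 and 1977 against 602 units in the hybrid. Over 6408 probe sets the log2 differences of these 2 pairs, which share no array, had a Pearson correlation of 0.319 and a Spearman correlation of 0.258, across probe sets that are not independent replicates. The counts of 3-fold differences depended on the floor and were 1133 in CF-1 and 1588 in the hybrid with a floor of 20 units.

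At 5 months the hybrid luteoma had 144 probe sets higher and 111 lower than its wild type. Luteal and LH response genes had a median of 0.69 over 11 genes (percentile 99.99), cholesterol genes of 0.95 (percentile 99.99) and endothelial genes of 0.98 over 7 genes (percentile 99.95). The mean log2 intensity of the luteal list in the luteoma, 11.868, lay within the range of the other wild types, 11.768 to 11.986. The wild type of this pair, at 11.289, was the lowest of the wild types for that list. Kdr and Tie1, receptors of endothelial cells, read 3357 and 2547 units in the luteoma against 922 and 483 units in the wild type, and Wnt4 read 3574 against 311 units. Macrophage genes were higher as well, with a median of 0.70 over 16 genes (percentile 99.99). Oocyte genes had a median of -1.19 over 5 genes (percentile 0.15) and smooth muscle genes of -0.87 (percentile 0.14). Granulosa genes had a median of -0.54 (percentile 0.06), and Inhbb read 711 against 5987 units and Inhba 1562 against 5891 units. Proliferation genes had a median of -0.74 over 26 genes (percentile 0.01). The 2 arrays of this pair belong to different control profiles, and no second pair can separate that from the luteoma. Across probe sets, this contrast had a Pearson correlation of -0.108 (Spearman -0.104) with the CF-1 tumour contrast and of -0.235 (Spearman -0.287) with the contrast of the hCG-treated luteoma against the CF-1 wild type, where the control profile enters the 2 contrasts with opposite signs.

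The hCG-treated ovary was set against the untreated CF-1 tumour to ask how the luteoma differs from the tumour in the same strain. The 2 differ in hCG treatment as well, and the tumour and the CF-1 wild type of 5 months have the shared control profile while the hCG array does not, so that pathology, treatment and profile cannot be separated in either hCG contrast. The hCG-treated ovary had 348 probe sets at least 3-fold higher and 261 at least 3-fold lower. Steroidogenesis genes had a median log2 difference of 1.67 over 7 genes (percentile 99.99), with Star at 22157 against 188 units, Hsd3b1 at 39329 against 1150 units and Cyp17a1 at 8023 against 1727 units. Cholesterol genes had a median of 1.21, epithelium and oviduct genes of 1.22 and luteal genes of 0.80, and immediate early and heat shock genes moved with them, at 0.98 (percentile 99.99). Proliferation genes had a median of -0.75 (percentile 0.02) and granulosa genes of -0.66 (percentile 0.20), with Inhba at 2909 against 12028 units, Inhbb at 1331 against 10279 units and Hsd17b1 at 2547 against 16047 units. Relative to the CF-1 wild type of 5 months the hCG-treated ovary had 135 probe sets higher and 115 lower. The median was 0.30 for steroidogenesis (percentile 92.83), 0.20 for luteal (80.35), 0.76 for theca and interstitial (99.6), -0.38 for granulosa (0.81) and -1.35 for adipocyte genes (0.01). It was -0.85 for macrophage genes, whose level in this wild type, 12.221, was the highest of all arrays.

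The hybrid luteoma compared with the CF-1 tumour, which differ in strain as well as pathology, had 219 probe sets higher and 152 lower. The median was 1.78 for cholesterol genes, 1.20 for luteal genes, 0.75 for steroidogenesis genes and -0.54 for granulosa genes. Other lists moved as well, with medians of 1.15 for endothelium (percentile 99.87), 0.61 for epithelium and oviduct (99.55), 0.425 for macrophage (99.45) and 0.36 for immediate early and heat shock genes (98.32). Oocyte genes had a median of 0.66 (98.41), proliferation genes of -0.39 (0.56) and extracellular matrix genes of -0.26 (1.41). Star and Ptgfr read 12108 and 11299 units in the hybrid luteoma, and Hsd3b1 read 1664 units, close to the 1150 units of the tumour. Hsd3b1 read 16166 units in the hybrid wild type of 2 months and 3612 in that of 5 months.

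The 2 luteomas were finally compared with the other 7 ovaries. Cpa3, a protease of mast cells, read 486 and 645 units in the hCG-treated and the hybrid luteoma and lay under the floor in the other 7, and Gsta3, a glutathione transferase, read 5043 and 6178 units and at most 2200 units elsewhere. Nnat, at -92 and 246 units, and the matrix gene Fbln1, at 972 and 850 units, were lower than in every other ovary, where they read at least 858 and 2076 units. An unnamed probe set, mentioned after its values were seen, read 11454 and 11256 units in the luteomas, 604 units in the tumour and at most 5551 units elsewhere. In all 5 probe sets met the 2-fold rule for this pair, 3 higher and 2 lower. Of the 36 possible pairs of arrays 7 had as many or more, and the highest was 9.

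For age, 1 of 6408 probe sets passed limma's threshold, an unnamed one that rose by a log2 difference of at least 1.90 (adjusted p = 0.034) at 5 months. It read 231, 126, 309 and 3 units at 2 months, 3 of them under the floor of 290.7, which shrinks the spread behind this p, and with a floor of 20 units the adjusted p was 0.199. It read 955 to 1314 units in the 4 untreated ovaries of 5 months, but 266 units in the hCG-treated ovary, which is as old. By unadjusted p under 0.05, 1252 probe sets differed, 617 higher and 635 lower. Of the oocyte genes, Zp2, a zona pellucida protein, read 447, 156 and 669 units in the CF-1 wild type, the tumour and the hybrid luteoma of 5 months. It read 309 units in the hCG-treated ovary, 1977 units in the hybrid wild type of 5 months and 2085 to 2595 units at 2 months. Age overlapped with the shared control profile, which 3 of the 4 untreated 5-month arrays had and 0 of the 2-month arrays. The hCG-treated array, also low for Zp2, does not have that profile. Age also overlapped with pathology, since the tumour and the hybrid luteoma were ovaries of 5 months, while the transgenic ovaries of 2 months were cystic. With a term for the profile, which leaves the age effect resting on the hybrid wild type of 5 months, limma passed 0 probe sets and 328 had an unadjusted p under 0.05. Without the hybrid wild type of 5 months, whose removal makes age and profile coincide, 254 passed, and without any 1 of the other 7 arrays 0 passed.

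For strain, 2 of 6408 probe sets passed, both higher in hybrids. Pop4, a subunit of ribonuclease P, rose by a log2 difference of at least 1.70 (adjusted p = 0.029), from 46 to 83 units in the 4 untreated CF-1 ovaries, all under the floor, to 532 to 703 units in the 4 hybrids. With a floor of 20 units, below all of these values, the adjusted p was 0.0255, and with the floor doubled it was 0.311. The other probe set, which is unnamed, rose by 1.93 ± 0.19 (SE; adjusted p = 0.029), but read 2839 units in the hCG-treated CF-1 ovary, above the 1381 to 2832 units of the 4 hybrids. By unadjusted p under 0.05, 505 probe sets differed between strains. With a term for the control profile, which here too amounts to leaving out the hybrid wild type of 5 months, limma passed 0, and 437 had an unadjusted p under 0.05. Without the tumour array 1 other probe set passed, lower in hybrids, and without any 1 of the other 7 arrays 0 passed, so that neither of these 2 passed with any 1 array left out.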

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

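Chosen only after the result was seen were the tests of the shared control profile as the cause of array similarity, of age, of missing tissue and of oviduct tissue, the check of opposite directions, the SD and the midpoint set against the genotype score, the limit that the control profile puts on the test of age, the count of steroidogenesis and luteal genes in the tumour, the reading of oviduct genes strain by strain, and their comparison at the floor. The count of steroidogenesis and luteal genes turned an open verdict into a firmer one, and the midpoint, the limit on age and the 2 choices on oviduct genes turned firmer verdicts into open ones. Within the 4 wild-type or the 4 transgenic untreated arrays, 7 of 58 checks put 1 array far from the other 3, where 2.9 are expected by chance. The tumour array was low for luteal and LH response genes, at a mean log2 intensity of 9.86 against 11.77 to 12.10 in the other transgenic arrays, and for cholesterol synthesis and uptake, at 10.08 against 11.76 to 11.86. The CF-1 wild-type array of 5 months was low for oocyte genes, at 8.98 against 10.38 to 10.48, and for proliferation genes, at 9.36 against at least 9.93, and high for macrophage and antigen presentation genes, at 12.22 against 10.65 to 10.89. The hybrid luteoma array was high for the macrophage list, at 11.53 against 10.58 to 10.70. The hybrid cystic array was high for the adipocyte list, at 9.49 against 9.08 to 9.11.

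In 3 of 38 checks, where 4.8 are expected by chance, both pairs of one kind moved against both pairs of the other, and these differences were not tested. The median genotype difference of the luteal list was 1.26 higher in hybrids than in CF-1, at 0.62 and -0.64, and that of the proliferation list differed by -0.62, at -0.41 and 0.20. The extracellular matrix list differed between 5 and 2 months by -0.20.

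The CF-1 wild-type array of 5 months lay closest, at r = 0.934 across probe sets, to the hybrid luteoma array, although it differs from it in genotype and strain. Age alone cannot be told apart, because the hybrid wild-type array of 5 months, which had r = 0.888 with the same luteoma array and 0.942 and 0.947 with the wild-type arrays of 2 months, is a single array and differs from the luteoma array in control profile. A shared processing of the CF-1 wild-type, tumour and hybrid luteoma arrays may contribute, since on 15 strand-control probe sets per chip type, which have no intended target, their correlations with each other were at least 0.951 and those with the other 6 arrays at most 0.878. A wrong genotype label cannot be told apart either, because a score from 100 probe sets chosen on the other 6 arrays put the array at 0.401, under the bound of 0.5 set before, but that bound belongs to the scale of the arrays used for choosing, and the midpoint between the means of the other wild types, at most 0.146 when held out, and of the transgenic arrays, at least 0.608, was 0.39, which is closer to the score than the SD of 0.0881 of those wild types. A difference between individual mice, such as their cycle stage, was not tested and stays open.

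The tumour array stood beyond every other array in more probe sets than any other array did. Shared processing and scaling are argued against as the whole cause, because at least 295 probe sets differed 3-fold between the tumour array and each of its control-profile mates against 138 between those mates, and because quantile normalization left a count of 57 against at most 17 for another array. Missing oviduct and fat tissue is argued against as the whole cause by the steroidogenesis and luteal lists. Of their 16 genes 6 were at least 3-fold lower than in the CF-1 wild type, against 118 of 3900 other genes (Fisher p = 5.52e-06, with genes taken as independent). This count was chosen after the result was seen, and not all 16 genes are particular to the ovary, Timp1 and Bhmt among the 6 being examples. Of the steroidogenesis genes alone 5 were lower and 2 higher, with Star at 188 against 18850 units. The luteal median of -1.22 had an interval from -5.93 to 0.11. The tumour itself, which the labels name, may account for the pattern and was not tested in a second animal.

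Epithelium and oviduct genes were lower in transgenic ovaries. Less oviduct tissue in the transgenic samples of 2 months cannot be told apart from a change in the ovarian cells, because Ovgp1 and Foxj1, markers of the oviduct, had a median log2 difference of 0.051 there against -1.18 for the other 10 members, but Ovgp1 alone was at -0.82 in CF-1 and Pax8, also of the oviduct, at -1.22 in CF-1 and -1.33 in hybrids. Pax8 lay under the floor in the cystic ovary of each strain, so its falls were at least that large. In the tumour sample it cannot be told apart from a change in the ovarian cells, because 6 of the 12 members, Ovgp1 among them at 109 units against at least 5823 units, lay below every other array, while Foxj1 lay under the floor in both the tumour and its wild type. The keratins of this list are also expressed by the ovarian surface. Whether the ovarian surface or ducts changed with LH was not tested.

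The real split of the 8 untreated arrays was set against the other splits, of which 33 could be fitted in each comparison, the real one included. For genotype the real count was 0, which all 33 of 33 splits must reach, with a highest other count of 0, so that this count decides nothing, and at an unadjusted p under 0.05 the real 642 was reached by 4 of 33 splits, with a highest other of 725, so that chance cannot be excluded. For age 2 of 33 gave at least the real count of 1, with a highest other count of 1, so that chance cannot be excluded for this count, and the other split as large did not keep the 3 arrays of the shared profile together. At an unadjusted p under 0.05 the real 1252 for age was reached by 1 of 33, the real one, with a highest other of 931. A share of 1 of 33 is the smallest these splits can give, and several counts were compared. It therefore argues against chance for that measure without excluding it, and leaves the overlap of age with the profile and with pathology. For strain 1 of 33, the real one, gave a count of 2, with a highest other count of 1, a margin of 1 probe set that does not exclude chance. Without the tumour 1 probe set passed, another one that was lower in hybrids, and the count was 0 without any 1 of the other 7 arrays, and at an unadjusted p under 0.05 the real 505 was reached by 4 of 33 splits, with a highest other of 723, so that for strain as a whole chance stays open.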

How the results depend on the processing

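Chosen after seeing the data were the term for the 3 arrays with a shared control profile, the removal of those arrays, the list tests without each array, and the tumour counts against the 6 or the 2 arrays without or with its profile. Only gene lists that had not passed reversed their test direction, and where a value moved the cause was not tested unless stated. The count of probe sets for genotype, 0, became 34 without scaling, 2 on the asinh scale and 8 with trend and robust variances, and ran from 0 to 7 when 1 array was left out, with 7 without the tumour, 2 without the CF-1 wild type of 2 months and 1 without that of 5 months. It stayed 0 in limma with quantile normalization, either other floor, no filter, the pair of strain and age as a block, no covariates, the hCG array added, the profile term and the profile arrays removed, with 330 to 731 probe sets at an unadjusted p under 0.05. Without scaling the median of all probe sets shifted by -0.16 for genotype and by -0.63 in the hybrid pair of 2 months, so those counts hold differences in array brightness. No further paired analysis was possible because the labels give no replicate numbers.

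The age count, 1, became 0 with quantile normalization, a doubled floor, trend and robust variances or the profile term, 18 without scaling and 3 without the filter, and ran from 0 to 254 with 1 array left out, 254 being without the hybrid wild type of 5 months. It stayed 1 with a floor of 20 units and on the asinh scale, but there the probe set was another one, lower at 5 months. The strain count, 2, became 6 without scaling, 1 with a floor of 20 units, 0 with a doubled floor, 6 without the filter, 1 with trend and robust variances and 0 with the profile term, and ran from 0 to 1 with 1 array left out, 1 being another probe set, lower in hybrids, without the tumour. The 5 lists that passed became 0 with an estimated correlation and 0 with fry, kept passing in camera with the other settings run, and were joined by others to a total of 5 to 8 with 1 array left out, 8 being without the CF-1 wild type of 5 months. With the profile term or without its arrays 7 lists passed. For named genes and single lists, 507 comparisons with an alternative kept their side of the threshold or size, 42 fell short of it, 27 newly passed it, 10 moved and 24 reversed.

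The 24 reversals were in 7 lists without a call, and the values here are median log2 differences, which can differ in sign from the test. With 1 array left out, macrophage genes, at 0.09 and downward with all arrays, ran from -0.119 to 0.361. They passed upward at 0.361 without the CF-1 wild type of 5 months (adjusted p = 0.0243) and downward at -0.119 without the hybrid wild type of 5 months (0.0319), so their direction rested on single arrays. None of the other reversals passed. Steroidogenesis genes ran from -0.161 to 0.119 and luteal genes from -0.116 to 0.296, both upward when one or the other CF-1 array of 5 months was left out. Granulosa genes ran from -0.205 to 0.174, proliferation genes from -0.246 to 0.082, ovulatory genes from -0.234 to 0.139, and cyclins D and their inhibitors from -0.014 to 0.213. Without the 3 profile arrays steroidogenesis (0.009), luteal (0.095) and macrophage genes (0.25) turned upward, and with the profile term granulosa (0.117) and proliferation genes (0.082) did. The ovulatory list turned downward with quantile normalization (-0.095), the granulosa list upward with the floor doubled (0.013), and the cyclin list downward with the mean of all probe sets of a gene (0.009).

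Counts by size followed the floor and the fold limit, as their construction requires, and low signal over background limits them. With a floor of 20 units the tumour count, 62, became 216 and the luteoma pair count, 5, became 23, and with the fold limit raised by 1.5 they became 18 and 1. Against the 6 arrays of another profile the tumour count was 98, and against the 2 of its own profile 164, where fewer arrays have to be exceeded. Of the 24 named tumour genes, 23 met the rule under every alternative at the same fold limit and 15 at the raised limit, and Tlcd4 did not with the floor doubled. Counts for pairs are given in the order CF-1 at 2 months, tumour, hybrid at 2 months, hybrid luteoma, hCG against wild type, hCG against tumour, hybrid luteoma against tumour. They were 40, 182, 64, 126, 98, 348 and 228 with the floor doubled. With a floor of 20 units they were 1133, 1139, 1588, 1754, 1908, 2490 and 1317, and with the raised fold limit 28, 122, 49, 82, 61, 202 and 154. The correlation of the 2 contrasts at 2 months, 0.319, was 0.294 without the filter.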

Other observations

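Apart from 1 list percentile, no test was run on the values given here, and the members of the lists named were chosen after their values were seen. Gdf9, an oocyte growth factor, read 1782 units in the CF-1 wild type, 1223 in the tumour, 1828 in the hCG-treated luteoma and 1865 in the hybrid luteoma, all of 5 months, and 3243 units in the hybrid wild type of 5 months and 3312 to 3790 units at 2 months. Zp3, of the zona pellucida, read 398, 146, 304 and 460 units in the same 4 ovaries and 1670 units in the hybrid wild type of 5 months. Of the proliferation genes, Cdk1 read 5978 units in the tumour, against 2948 units in its wild type and 3481 to 5273 units in the other ovaries. Stmn1 read 2041 units in the tumour and 813 in its wild type, but 1672 to 1865 units in the other 3 wild types. The proliferation list had a median log2 difference of 0.348 between tumour and wild type (percentile 99.79), but its mean log2 intensity in the tumour, 9.793, lay under the other 3 wild types, at 9.926 or more, the wild type of the pair being low at 9.358.

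Wnt4 was measured by 2 probe sets on chip B. On one it read 2318, 1977 and 3574 units in the CF-1 cystic, hybrid cystic and hybrid luteoma ovaries, and 311 to 745 units in the 4 wild types. It lay under the floor in the tumour and read 726 units in the hCG-treated luteoma. The second probe set read 2007, 1516 and 4550 units in the first 3 ovaries and 752 units in the hCG-treated one. Within the macrophage list, the class II gene H2-Aa read 1386 and 2114 units in the cystic ovaries against 4214 and 6136 units in their wild types, while the complement gene C1qb read 2616 and 2961 units against 2034 and 2482 units. The direction for C1qb depended on the probe set. On another it read 2192 and 2210 units against 1883 and 2126 units, and on a further one 953 and 849 units against 1003 units in each wild type. The hemoglobin gene Hba-a1 read 47516 units in the hybrid cystic ovary and 38313 units in the hCG-treated one, against 10591 to 24040 units in the other ovaries. These 2 arrays also had the highest deposited maxima on chip B, 41833.2 and 38448.8 units, against at most 30450.7 units on the other 7.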
